A study of Loxodonta africana with 4 samples.

How the data were processed

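Total RNA from PBMC of adult female African bush elephants was sequenced in 4 libraries. Per the labels' protocols, the cells were separated on a Ficoll-Paque density gradient with 3 washes, and libraries were made with the Illumina TruSeq Stranded RNA kit and Ribo-Zero Gold, which removes ribosomal RNA and keeps transcripts without a poly(A) tail. The authors deposited a table of whole-number counts per gene, 1 column per library, with no normalization. The submitters' processing notes name STAR, RSEM, featureCounts and edgeR, without a version or the role of each. The genome build, the annotation release, the treatment of reads that match several genes and the strand setting of the counting are not given in the sources used here. Reads of near-identical gene copies or of overlapping genes could therefore have been split or dropped in ways that the counts do not show.

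Columns were assigned to samples by the number that the column name and the sample title share. The table holds 1 further column that matches no sample analysed here, and it was not used in any step. All rows carry a gene identifier of the ENSLAFG form, and no row is a summary of unassigned reads. None of the 23245 identifiers matched the gene table for the mLoxAfr1.hap2 assembly, which lists symbols and RefSeq accessions. The 46 lists of cell type markers and pathways that were fixed before the data were examined could not be applied, and results for them are not given. The rule for naming genes, also fixed then, took the genes with a symbol that had the highest level, the largest and smallest spread or a place in a list. It names none of these rows, so 4 identifiers were singled out after seeing the values: the most counted gene and the 3 genes with the largest SD of log2 CPM among those with a mean of at least 10 CPM. Gene lengths and positions were not used, so levels compare a gene between libraries, not genes of different length with each other.

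Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and an intercept-only design, which left 12430 genes, 53.5% of the table, holding 99.95% of the counts. Libraries were scaled by TMM, with factors from 0.978 to 1.01, and log2 CPM used a prior count of 2. The BCV was estimated with estimateDisp for the 4 libraries and with estimateCommonDisp for each pair. For the test of variability, a quasi-likelihood model (glmQLFit, robust) was fitted with an intercept only. Each gene's deviance over its 3 residual degrees of freedom was divided by the fitted trend and set against an F distribution with 3 and 4.68 degrees of freedom, one-sided, with Benjamini-Hochberg adjustment. The second number is the prior degrees of freedom of genes not treated as outliers by the robust fit. Dixon's ratio was computed on log2 CPM. Shares of counts carry 95% exact binomial intervals, and the limit for a gene with no count is 3 counts of the total. PCR copies are not independent molecules, so these cover counting error alone.

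Depth ran from 37222717 to 44018016 counts per library, where 3 counts correspond to 0.0806 and 0.0682 CPM. The scripts were tested on simulated data for the 12430 genes, with the real mean levels and library sizes and gene-wise spreads drawn around the fitted trend. A single library was changed by a known fold in 50 genes for each of 4 folds. The test of variability called 1 of 50 genes changed 2-fold, 37 of 50 changed 4-fold, 46 of 50 changed 8-fold and 50 of 50 changed 16-fold, and 11 of 12230 unchanged genes. The changed genes of all 4 folds shared 1 simulated set, which eases the Benjamini-Hochberg threshold for each of them. A lone changed gene would be called less often, so these counts are not the power of the test in the real data. Dixon's ratio picked the changed library at 18, 33, 40 and 45 of the 50 genes in the same order of folds. A common BCV of 0.120 was obtained from simulated libraries without changed genes, against 0.117 in the data that they were modelled on.

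With 1 group there is no test between groups. Alternatives covered the scaling (DESeq2 1.42.0 size factors, total counts), the expression filter, the prior count, the robust setting, DESeq2's dispersions and leaving out each library. Cyclic loess for a check in the closing section came from limma 3.58.1.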

Results

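RNA sequencing counts were examined for 4 libraries of peripheral blood mononuclear cells (PBMC), the lymphocytes, monocytes and related white cells that a density gradient separates from blood, from adult female African bush elephants. The libraries were numbered 1, 3, 7 and 14 in the sample titles and formed 1 group. The labels did not say whether each number was a separate animal, so the errors below measure the spread between these libraries, which may be partly technical. The stated purpose of the series was to find genes expressed differently between Asian and African elephants. Asian elephant samples were not analysed here, so the data bear on the African side of that comparison: which genes were counted in these cells, at what level, and how far the libraries differed from each other. The table named genes by identifier alone and none of its 23245 identifiers matched the gene table used for names, so no gene is named by symbol and no cell type or pathway could be assessed.

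The libraries were deep and of similar size. The genes of the table took 41710334 counts in library 1, 37222717 in library 3, 44018016 in library 7 and 42586692 in library 14. Of the 23245 genes in the table, 14927 had a count in all 4 libraries, 5444 in some but not all of them, and 2874 in none. A gene with no count in any library lay below 0.0181 CPM, the usual unit of counts scaled to library size, which is the level of 3 counts over the 4 libraries together, a limit that covers counting error alone. At least 10 counts were reached by 12898 ± 47.3 genes per library (SD, n = 4). Any count at all was reached by 17388 ± 719 genes per library (SD, n = 4), from 16659 in library 3 to 18343 in library 1. At 1 CPM the order of these libraries turned, with 11319 genes in library 3, the most, and 11136 in library 1, the fewest.

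Counts, not adjusted for gene length, were concentrated in a small part of the gene catalogue, and the leading genes were shared between libraries. The 10 most counted genes held 9.56% ± 0.516 of all counts (SD, n = 4), the 100 most counted held 25.4% ± 0.799 (SD, n = 4) and the 1000 most counted held 59.2% ± 0.627 (SD, n = 4). In all, 84 genes stood among the 100 most counted of every library and 8 among the 10 most counted of every library. The mean level was at least 1 CPM for 11242 genes, at least 10 CPM for 8017, at least 100 CPM for 2174 and at least 1000 CPM for 92.

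The most counted gene, ENSLAFG00000024050, took 3.605% of the counts in library 1, with a 95% exact Clopper-Pearson interval of 3.599 to 3.610. The share was 3.827% in library 3 (3.820 to 3.833), 4.003% in library 7 (3.997 to 4.009) and 3.881% in library 14 (3.875 to 3.887). These intervals cover counting error and do not overlap, so the libraries differed by more than that error. Its mean level was 38290 ± 1267 CPM (SD, n = 4), and the next gene averaged 8199 CPM. Neither level is adjusted for gene length, so the difference between the 2 genes is one of counts. The highest library exceeded the lowest by 1.08-fold. The gene was singled out after its values were seen.

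The expression profiles of the 4 libraries were close to each other. Across the 12430 genes that passed the expression filter, Pearson's correlation of log2 CPM for the 6 pairs ran from 0.991 between libraries 1 and 7 to 0.997 between libraries 7 and 14, and Spearman's from 0.993 to 0.998 for the same pairs. These correlations are across genes, which are not independent replicates. Every pair differed by more than sampling noise. The chi-square of the counts over its degrees of freedom, which is near 1 for repeat samplings of a single library, was 13.7 for libraries 7 and 14 and between 24.2 and 67.3 for the other 5 pairs. Each library was counted as 1 sample. A second preparation from the same animal would also exceed sampling noise, so these values do not show whether any libraries share an animal.

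Libraries 7 and 14 differed least. The biological coefficient of variation (BCV), the relative spread beyond counting noise, was 0.0506 for this pair. It was 0.0923 for libraries 1 and 3, and between 0.125 and 0.146 for the remaining 4 pairs. A difference of at least 2-fold separated 35 genes between libraries 7 and 14, and between 127 and 208 genes in each other pair. The first principal component carried 56.8% of the variance and placed libraries 1 and 3 at −18.39 and −13.18, and libraries 7 and 14 at 17.81 and 13.76. Each pair holds a single library on either side, so these differences carry no test.

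**Figure D1:**
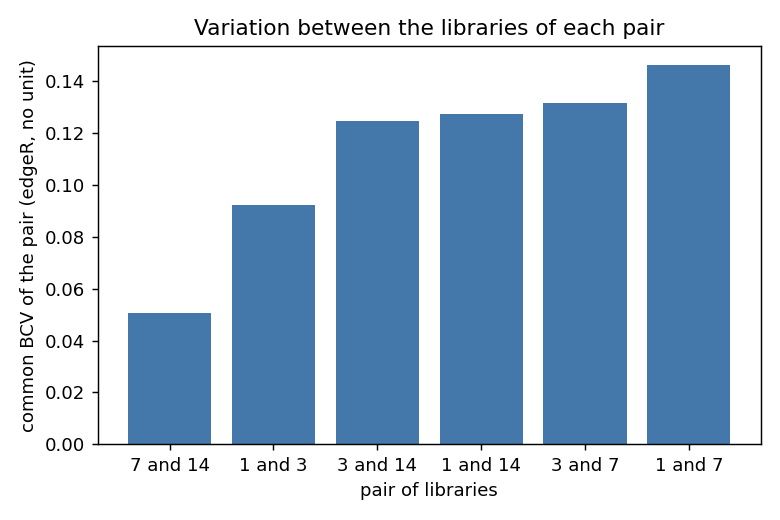
Common biological coefficient of variation (vertical axis, no unit, from 0) for each of the 6 pairs of African bush elephant PBMC libraries, 1 bar per pair, over 12430 genes. The bar for libraries 7 and 14 is at 0.0506, the lowest, and the bar for libraries 1 and 7 at 0.146 is the highest.

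Most genes varied little between libraries. Over all 4 libraries the common BCV was 0.117, and the median gene's highest library exceeded its lowest by 1.25-fold. The range reached 2-fold for 485 genes, 3.90% of those kept, and 4-fold for 16. The spread depended on the level. Classes of level were cut here by the mean of log2 CPM, so their sizes differ slightly from counts of genes by mean CPM. Genes below 1 CPM had a median SD of 0.324 on the log2 scale and a median BCV of 0.167. Counting noise alone has a theoretical SD of 0.293 at their median of 24.2 counts. The median of SDs taken over 4 libraries tends to fall below the theoretical value, so the values are not like for like. Genes between 10 and 100 CPM had a median SD of 0.117 and a median BCV of 0.0953, with a theoretical counting noise of 0.0394 at their median of 1343 counts. The spread did not keep falling above that level. The median SD was 0.117 between 100 and 1000 CPM and 0.139 at 1000 CPM and above, and the share of genes with a range of at least 2-fold was 0.479% between 10 and 100 CPM, 0.771% between 100 and 1000 CPM and 2.22% (2 of 90 genes) at 1000 CPM and above. By the mean of CPM instead of log2 CPM, 8017 genes had a mean of at least 10 CPM, and 47 of them had a range of at least 2-fold. Counting noise was thus a large part of the spread for the faintly counted genes, where small differences between libraries are hard to resolve. For the abundant genes the spread was well above counting error.

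**Figure D2:**
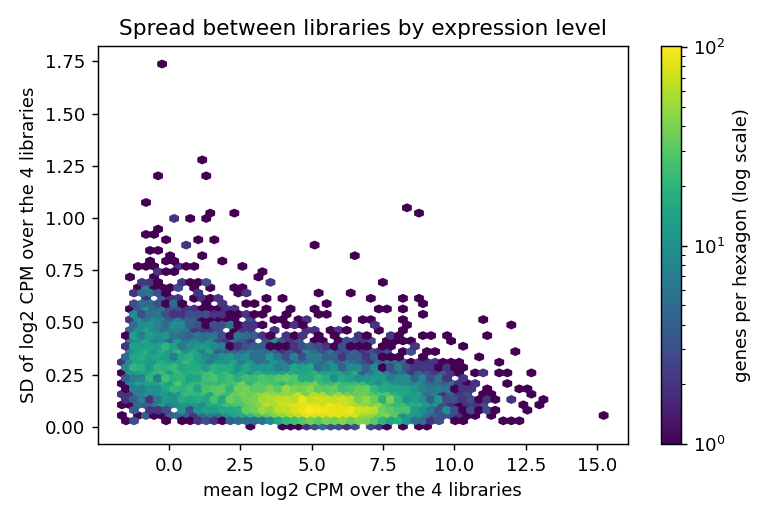
Standard deviation of log2 CPM over the 4 libraries (vertical axis) against the mean log2 CPM (horizontal axis) for 12430 genes, with the shade of each hexagon giving the number of genes on a log scale. The spread is widest at low levels, and the median SD falls from 0.324 below 1 CPM to 0.117 between 10 and 100 CPM, with 0.139 at 1000 CPM and above.

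Among genes with a mean of at least 10 CPM, the 3 with the largest spread were singled out after their values were seen. ENSLAFG00000015821 stood at 118.4 CPM in library 1, 658.3 in library 3, 430.9 in library 7 and 376.9 in library 14, a mean of 396.1 ± 221.7 CPM (SD, n = 4). ENSLAFG00000021656 followed the same order, at 161.1 CPM in library 1, 871.2 in library 3, 547.8 in library 7 and 486.0 in library 14. The highest library exceeded the lowest by 5.56-fold for ENSLAFG00000015821 and 5.41-fold for ENSLAFG00000021656. Without library 1 the ranges were 1.75-fold and 1.79-fold, and without library 3 they were 3.64-fold and 3.40-fold. ENSLAFG00000016505 went the other way, at 86.9 CPM in library 1 and 24.4, 25.8 and 30.5 CPM in libraries 3, 7 and 14. Its range was 3.56-fold, and 1.25-fold without library 1.

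Whether any gene varied more than genes of its level do was tested with edgeR's quasi-likelihood dispersions and Benjamini-Hochberg adjustment. No gene of the 12430 passed an adjusted p of 0.05 (smallest adjusted p 0.970), and 555 genes, 4.47%, lay under an unadjusted p of 0.05. The trend and the prior degrees of freedom were fitted to these same genes, so a share near that level follows largely from the fit. The count depended on the method and on whether the faintest genes entered the fit. With every counted gene in edgeR's fit, 133 genes passed, 130 of them among the 12430. The prior degrees of freedom of the F test were then 27.5, against 4.68 with the filter. DESeq2, run on the same 12430 genes, marked 44 as dispersion outliers, by a rule that uses no adjusted p and is not like for like with edgeR's test. The 3 genes with the largest spread were in both edgeR's set without the filter and DESeq2's set. Their adjusted p values in edgeR's test without the filter were 4.1e-07 for ENSLAFG00000015821, 7.35e-07 for ENSLAFG00000021656 and 3.17e-07 for ENSLAFG00000016505, against 0.970 for each with it. These genes were picked for their spread in the same counts, so their place in the sets is not separate support.

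Genes at which a single library stood apart from the other 3 were counted with Dixon's ratio at its 95% critical value for 4 samples. There were 562 such genes, 4.52% of those kept, where the test's level gives 5% by chance. Simulated libraries with the same levels and depths, and with gene-wise spreads drawn at random around the fitted trend, gave a mean of 634 genes, from 568 to 698 in 100 sets. Library 1 stood apart at 225 genes, 98 above and 127 below the others. Library 3 stood apart at 201 genes, 106 above and 95 below. Library 7 stood apart at 76 genes and library 14 at 60. In the simulated sets the count per library ran from 129 to 190 for library 1, from 132 to 208 for library 3, from 120 to 199 for library 7 and from 116 to 190 for library 14. Genes varied independently in the simulation, so these ranges are narrower than for libraries whose genes vary together and give no test of a library. The low counts of libraries 7 and 14 also restate their closeness, since neither can stand apart where the other lies beside it. A gap of at least 2-fold to the nearest other library was seen at 10 of the 562 genes, 8 of them in library 1 and 2 in library 7. The simulated sets had 13 to 33 such genes, a number that depends on the spreads drawn.

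**Figure D3:**
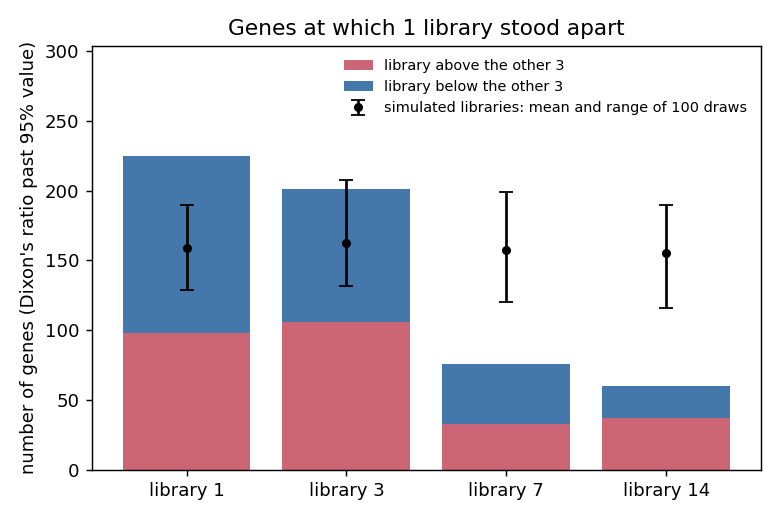
Number of genes (vertical axis) at which each library (horizontal axis) stood apart from the other 3, split into genes where it was above and below. Black points and bars give the mean and range of 100 simulated sets in which genes vary independently, and the bars reach 225 genes for library 1, 201 for library 3, 76 for library 7 and 60 for library 14.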

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

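The common BCV was 0.117 and stayed between 0.108 and 0.118 under the other scalings, filters and DESeq2's dispersions, and between 0.108 and 0.126 when each library was left out in turn. The mean correlation of the pairs was 0.993 to 0.994 without each library, a measure too near its ceiling to show a change. The number of genes with a mean log2 CPM of at least 0 ran from 11243 to 11310 without each library, against 11271 with all 4. Other scalings cannot move it, because their factors multiply to 1. Genes detected per library averaged 12898 at 10 counts and 11224 at 1 CPM, a stricter limit at these depths. The count of genes more variable than the trend was 0 with the filter in edgeR, under both other scalings, without the robust setting, at a mean of at least 10 CPM, and without each library (0 in each case). Genes at an unadjusted p under 0.05 numbered 336 at a mean of at least 10 CPM and 472 to 627 without each library. The count of genes more variable than the trend was 133 without the filter. DESeq2's outlier rule marked 44 of the 12430 genes. That rule uses no adjusted p, so its number is not like for like with edgeR's. The prior degrees of freedom were 27.5 without the filter and 4.68 with it, and 130 of the 133 genes were among the 12430 tested with it. All 44 DESeq2 genes had an unadjusted p under 0.05 in edgeR, and 43 were among the 130. Of these 130 genes, 63 were farthest from the median in library 1, 29 in library 3, 21 in library 7 and 17 in library 14. The number of genes at which a library stood apart was 562, and 551, 544 and 561 with DESeq2 size factors, total counts and a prior count of 0.5. It was 3418 without the filter, of which 527 were among the genes kept. Without the filter, a gene counted in a single library stands apart by construction, since the libraries with no count share 1 value. Such genes numbered 1023 in library 1, 355 in library 3, 600 in library 7 and 444 in library 14. At a mean of at least 10 CPM a library stood apart at 294 of 8017 genes, against 562 of 12430 in the main setting. Alternatives planned for gene lists, list differences, list variability and gene length were not run, since no identifier had a symbol or length. No paired analysis was possible because the 4 libraries form 1 group. Depth limits the genes below 1 CPM, where a theoretical counting noise of 0.293 is large beside the median SD of 0.324, although these measures are not like for like.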

Other observations

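The tests of the closeness of libraries 7 and 14 and of the genes counted in library 1 were chosen after those patterns were seen, and before the tests' own values were computed. The comparison of totals was added after those results were seen. Of 15 values compared over the libraries with Dixon's ratio, including the totals, the shares of counts and the levels of the 4 singled-out genes, 0 had a library apart at the 95% level. ENSLAFG00000016505 came nearest, at a ratio of 0.825.

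Libraries 7 and 14 differed from each other by a root mean square of 0.205 on the log2 scale over genes, 0.705 times the smallest value of the other 5 pairs. No error over samples can be given for this ratio, since each pair is 2 libraries and genes vary together. Depth as the whole cause was argued against. The ratio was 0.725 after thinning all libraries to 37222717 counts (0.715 to 0.733 over 20 draws). Libraries 1 and 14, whose totals differ by 876358 counts, were not as close as libraries 7 and 14, whose totals differ by 1431324. A trend with level as the whole cause was argued against by a ratio of 0.737 after cyclic loess normalization. A smaller part of either is not excluded, since both ratios lie above 0.705. Whether the closeness rests on the most abundant genes was not decided. This measure weighs all genes alike, so removing 100 genes of 12430 can hardly move it. Without the 100 most counted genes the ratio was 0.712, and no pair moved by over 0.74%. Measures that weigh genes by their counts were not checked in this way. A shared preparation, day or animal relation may underlie the closeness. It cannot be told apart from other differences between the blood samples, because 0 labels other than the title split the 4 libraries.

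Library 1 had a count in 18343 genes, more than libraries 7 (17478), 14 (17071) and 3 (16659), although it was not the deepest. Depth was argued against: after thinning to the smallest total, library 1 still exceeded the next library by 942 genes. Low-level reads spread over barely counted genes may contribute, and this stays open. The 10815 genes outside the filter held 544.6 CPM in library 1, against 450.9 in library 3, 441.0 in library 7 and 426.0 in library 14, but this measure overlaps with the count of genes itself and so decides nothing.

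The genes with the largest and second largest spread kept a narrow ratio in every library. ENSLAFG00000021656 stood at 1.36 times ENSLAFG00000015821 in library 1, 1.32 times in library 3, 1.27 times in library 7 and 1.29 times in library 14, while each ranged over 5-fold between libraries. Both genes were picked for their spread in these same libraries, and ratios of other genes were not computed. The narrow ratio is therefore a description and shows no link between the genes.

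Among the 100 genes with the highest mean level, the median departure from the mean of the 4 libraries was 0.05 on the log2 scale in library 1, −0.07 in library 3, 0.01 in library 7 and −0.02 in library 14. In the tenth of kept genes with the lowest levels the order of libraries 1 and 3 turned, at −0.06 and 0.09.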
